A study of Mus musculus with 4 samples.

How the data were processed

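RNA from 4 precipitates of mouse 4T1 mammary carcinoma cells was sequenced, 1 library each for IgG and for Caprin-1 from cells with the control shRNA and from cells with the CerS4 shRNA. The cells grew in medium with puromycin, RNA was harvested with Qiazol, and libraries were built from polyadenylated RNA with a SMARTER mRNA kit, per the labels' protocols. Reads were aligned to the mm10 build with STAR in Partek, with no tool version given, per the submitters' processing notes. The strand of the reads was not stated.

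The deposited table held CPM values per transcript although its name calls them raw counts, and the design made before the values were seen had assumed counts. Each deposited CPM column had an added 0.0001 per transcript, which was subtracted. The CPM worth of 1 read was recovered from the spacing of the values, which gave estimated depths of 19.8, 27, 19.7 and 24.7 M reads for shSCR IgG, shSCR Caprin-1, shCerS4 IgG and shCerS4 Caprin-1. Reads were shared among transcripts, so not all values were whole numbers of reads. Under 40 CPM, 32.6%, 29.8%, 31.7% and 30.5% of transcript values and 81.7%, 80.3%, 81.7% and 80.4% of gene values lay within 0.05 reads of a whole number. A total of 3 reads corresponded to 0.151, 0.111, 0.152 and 0.122 CPM.

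The 24393 transcripts were summed into 12967 gene symbols, of which 7415 had 1 transcript. Of these symbols 12957 matched the gene reference, 2 matched by a synonym and 8 did not match. Positions are those of GRCm38. Genes with a mean of at least 5 CPM over the 4 libraries were compared, 10283 in number. Log2 ratios were computed after scaling to total counts, with 0.5 reads added to each estimated count. The 95% counting interval came from the estimated reads alone. These are reads after amplification, without molecular barcodes, so the interval covers neither amplification nor variation between cultures. A gene was counted as past 2-fold when its ratio was at least 2-fold and its interval excluded 0. The median distance from a ratio to the end of its interval was 0.129 for the Caprin-1 precipitates, 0.137 for the IgG precipitates and 0.189 for the difference of the Caprin-1 over IgG ratios.

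The comparisons were shCerS4 over shSCR in Caprin-1 precipitates and in IgG precipitates, Caprin-1 over IgG in each cell line, and the difference between the last 2. With 1 library per group no significance test was made. Gene lists were written from general knowledge before the values were seen. The median of each list with at least 3 measured genes was ranked among 10000 random lists drawn from the same bins of mean expression, of which there were 20, and a list outside the 2.5 to 97.5 percentiles was called outside. Of 105 list medians, 48 lay outside, where 5.2 would if list members were unrelated genes. Genes of a list can vary together and the 5 comparisons share libraries, so this excess measures no significance.

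Genes were named by a rule fixed in advance. It took Cers4, Shh, Cd274, Caprin1, Tgfbr1, Ctnnb1, Myc, Ccnd2 and G3bp1 always, of which Cers4 and Shh had no values. Among genes past 2-fold with a mean of at least 20 CPM and a symbol that is not a predicted gene, it took the 10 highest and 10 lowest ratios of the Caprin-1 precipitates, the 8 highest and 8 lowest over IgG in each cell line and of the difference, and the 5 highest and 5 lowest of the IgG precipitates. From each list it took the most abundant gene and up to 4 with the largest ratio in a comparison, with a mean of at least 5 CPM. Cdk6, the end of a run of genes on chromosome 5, was named after the values were seen. A few genes that the rule names are not reported here.

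The scripts were tested on simulated data with 10258 genes and counting noise alone, without amplification or variation between cultures. The intervals held the true ratio for 95.4% of genes in the Caprin-1 precipitates, 95.4% in the IgG precipitates and 94.8% for the difference of the ratios. No unchanged gene passed the 2-fold rule in any of these, which checks the calculation and gives no false positive rate for real libraries. All genes changed 3-fold passed in the Caprin-1 precipitates and in the difference, and 0.0% and 1.0% of genes changed 1.5-fold passed. In the simulated IgG precipitates 3 of 40 unchanged lists lay outside, and a list shifted by 0.3 had percentile 100. Over 12967 genes trimmed-mean scaling gave unchanged genes a median of −0.003.

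Alternatives tried were trimmed-mean, median-of-ratios and upper-quartile scaling, each written for this work, totals without the 50 most abundant genes and ribosomal RNA, filters of 1 CPM, 20 CPM and none, 5 added reads, thinning to equal depth and no interval. The trimmed mean left out 30% of the log ratios and 5% of the abundances on each side. After seeing the data, the most abundant transcript per gene, leaving out the chromosome 5 genes, and random lists matched on the Caprin-1 over IgG ratio or on genomic span were added. The planned trend on transcript length and GC was not run, since the reference gave neither. No deposited column was left out. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.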

Results

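RNA immunoprecipitation followed by sequencing was used to ask which mRNAs are bound by Caprin-1, an RNA-binding protein of stress granules, when lipid metabolism is altered. The cells were 4T1, a metastatic mammary carcinoma line from BALB/c mice. They stably expressed either a control shRNA (shSCR) or an shRNA against CerS4, the ceramide synthase 4 enzyme of sphingolipid synthesis (shCerS4). From each cell line, RNA was recovered with an antibody against Caprin-1 and, as the background control, with IgG. The study set this work in the context of a complex of Caprin-1 with PD-L1, the immune checkpoint ligand encoded by Cd274. There was 1 library per group, 4 libraries in all, so no difference below has a replicate check. Each interval in brackets is a 95% counting interval of the log2 ratio, and it covers counting error between these libraries only.

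The estimated depth, was 19.8 M reads for the shSCR IgG library, 27 M for shSCR Caprin-1, 19.7 M for shCerS4 IgG and 24.7 M for shCerS4 Caprin-1. Of 12967 gene symbols, 10283 had a mean of at least 5 CPM (read counts scaled to the library total) over the 4 libraries and were compared. The deposited values held no entry for Cers4, the target of the knockdown, or for Shh, the sonic hedgehog ligand, so the knockdown could not be checked. Every transcript with an entry reached at least 10.0 estimated reads in some library, so transcripts below such a level may be absent from the deposited values.

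Among the 7 measured genes that were to be named whatever their values, Cd274 was the one whose mRNA was lower past 2-fold in shCerS4 cells. It stood at 377 CPM in the Caprin-1 precipitate of shSCR cells and 127 CPM in that of shCerS4 cells, a log2 ratio of −1.57 [−1.63, −1.51]. In the IgG precipitates it stood at 324 and 101 CPM, a log2 ratio of −1.68 [−1.76, −1.61]. Its Caprin-1 over IgG ratio was therefore small in both cell lines, at 1.17-fold in shSCR and 1.26-fold in shCerS4 cells. Caprin1 mRNA, which encodes the precipitated protein, was 1.26-fold lower in shCerS4 cells in the Caprin-1 precipitates and 1.36-fold lower in the IgG precipitates. G3bp1, which encodes the stress granule partner of Caprin-1, was 1.70-fold and 1.69-fold lower, with Caprin-1 over IgG log2 ratios of 0.02 and 0.01 in shSCR and shCerS4 cells.

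Caprin-1 precipitates of shCerS4 and shSCR cells were then compared, which was the main comparison of the study. Past 2-fold, 21 of 26 DNA replication genes and 16 of 24 genes of G2 and mitosis were lower in shCerS4 cells, and 10 of 23 genes of secreted and matrix proteins were higher. Among genes with a mean of at least 20 CPM and a symbol that is not a predicted gene, the lowest ratios belonged to Abcb1a and Abcb1b, which encode the P-glycoprotein drug exporter, at log2 ratios of −5.24 [−5.62, −4.90] and −4.88 [−4.97, −4.80]. The highest belonged to Cdsn, which encodes the adhesion protein corneodesmosin, at 5.05 [4.65, 5.52], followed by the tight junction gene Cldn3 at 4.22 and the neutrophil chemokine gene Cxcl1 at 4.17. In all, 643 of the 10283 genes were higher and 509 lower past 2-fold with an interval that excluded 0. The balance turned to 442 against 639, 458 against 617 and 484 against 590 under trimmed-mean, median-of-ratios and upper-quartile scaling. Others among the 10 highest of that set included Cask (4.16), Stbd1 (3.96), the chemokine gene Cxcl5 (3.6), Tmc4 (3.45), C1s1 (3.41) and the transcription factor gene Cebpd (3.35). The other genes among its 10 lowest were Elapor2 (−4.63), Dbf4 (−4.26), Sri (−3.93), the matrix protein gene Mgp (−3.90), Cldn9 (−3.88), Steap4 (−3.81), Rundc3b (−3.78) and Tmem243 (−3.66).

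Of the 1152 genes past 2-fold, 1135 (98.5%) had the same direction in the IgG precipitates with an interval that excluded 0. Abcb1a had an IgG log2 ratio of −5.0 and Abcb1b of −4.97, and among the highest genes the IgG log2 ratio was 3.75 for Cdsn, 4.05 for Cldn3 and 4.32 for Cxcl1. In the IgG precipitates 585 genes were higher and 549 lower past 2-fold in shCerS4 cells, and 475 and 620 under trimmed-mean scaling. Of the 643 genes higher in Caprin-1 precipitates, 396 were also past 2-fold in the IgG precipitates, where independent lists would share 36.6. Of the 509 lower genes, 413 were shared, where independent lists would share 27.2, and no gene was past 2-fold in opposite directions. Across genes, which are not independent replicates, the log2 ratios of the 2 precipitates had a Pearson correlation of 0.89 and a Spearman correlation of 0.83. The 2 ratios share no library.

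**Figure D1:**
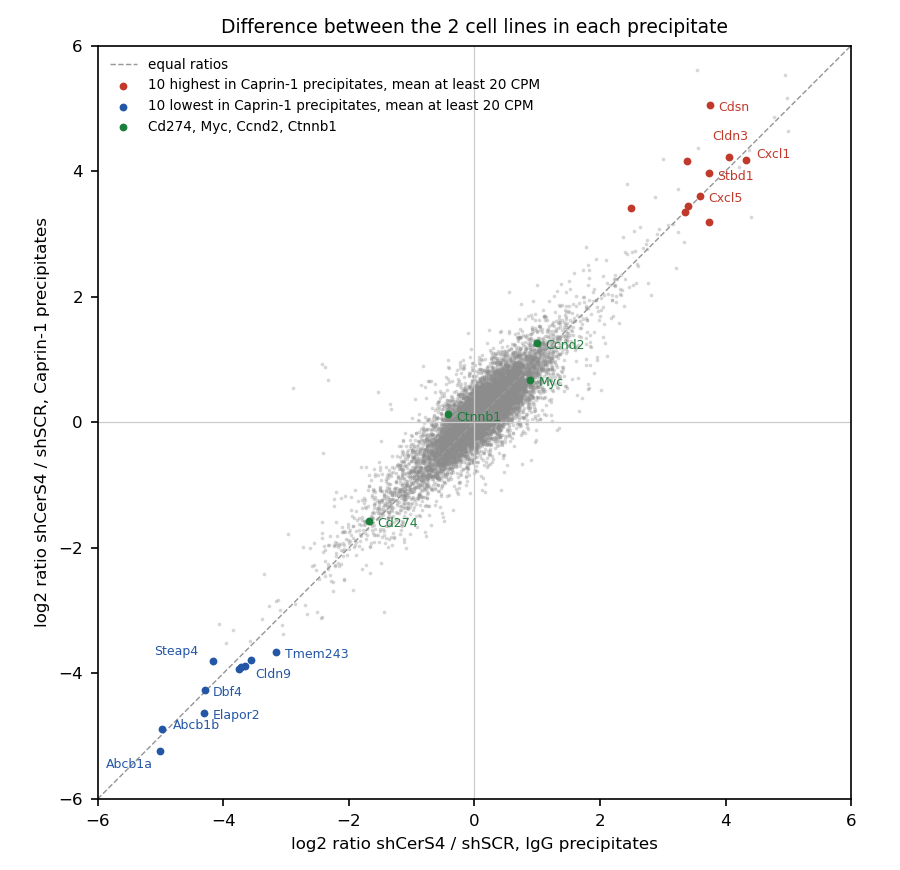
Each point is 1 of the 10283 genes, with its shCerS4 over shSCR log2 ratio in the IgG precipitates on the horizontal axis and in the Caprin-1 precipitates on the vertical axis. Genes lie along the line of equal ratios (Pearson correlation 0.89), Abcb1a and Abcb1b at the low end and Cdsn, Cldn3 and Cxcl1 at the high end.

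DNA replication genes formed the list with the lowest median in the Caprin-1 precipitates, a log2 ratio of −1.51 over 26 measured genes, 21 of them lower past 2-fold and none higher. Among them were Cdc6, a licensing factor of replication origins, at −3.31, Rrm2, a subunit of ribonucleotide reductase, at −2.90, the DNA ligase gene Lig1 at −2.02 and the helicase gene Mcm3 at −1.97. Genes of G2 and mitosis had a median of −1.15, with 16 of 24 lower and none higher, including Birc5 (−2.12), Aurkb (−1.86), Plk1 (−1.54) and Cenpf (−1.53). Both medians lay below all 10000 random lists matched on mean expression (percentile 0.00). In the IgG precipitates the medians of the 2 lists were −1.65 and −1.25. Genes of cholesterol and fatty acid synthesis had a median of −0.64 (percentile 0.00), with 9 of 27 lower and none higher. They included Insig1 at −1.53, the lipogenic regulator gene Srebf1 at −1.26 and Cyp51 at −3.14, and the IgG median was −0.91.

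Secreted and extracellular matrix genes had the opposite direction, with a median log2 ratio of 0.80 in the Caprin-1 precipitates (percentile 100) and 10 of 23 genes higher past 2-fold. Besides Cxcl1 and Cxcl5, the cytokine gene Il1a stood at 4.01 and the chemokine gene Ccl20 at 2.69, and no member was lower past 2-fold. The IgG median of this list was 0.34 (percentile 98.36). Unfolded protein and integrated stress response genes had a median of 0.51 (percentile 100), with 6 of 30 higher, among them Atf3 (3.15), Ppp1r15a (2.28), Ddit3, which encodes the stress factor CHOP (2.22), and Trib3 (1.36). Interferon response and antigen presentation genes had a median of 0.48 (percentile 99.93), with 4 of 34 higher, including Usp18 (2.03) and Rsad2 (1.68). Among 13 nuclear-retained and structural long non-coding RNAs the median was 0.99 (percentile 100). The 6 that were past 2-fold included the snoRNA host genes Snhg12 (2.10), Snhg5 (1.94), Snhg17 (1.64) and Zfas1 (1.47), whereas Malat1 (−0.09), Norad (0.30), Firre (0.36) and Neat1 (0.84) were under 2-fold.

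Sphingolipid enzyme genes, the pathway of the knockdown target, had a median log2 ratio of 0.37 in the Caprin-1 precipitates (percentile 97.74), with 4 of 31 higher and 1 lower past 2-fold. Sgpl1, which encodes sphingosine-1-phosphate lyase, stood at 1.12, the sphingosine kinase gene Sphk1 at 1.08 and the fatty acid elongase gene Elovl6 at −1.12. Cers2, the most abundant member of the list, stood at 0.68. B4galt6, a lactosylceramide synthase gene, had 3 estimated reads in the shSCR Caprin-1 library and 327 in the shCerS4 Caprin-1 library, a log2 ratio of 6.68 [5.34, 9.19]. In the IgG libraries it had 2 and 573 estimated reads, a log2 ratio of 7.85 [6.31, 11.22]. It passed the filter of 5 CPM through the shCerS4 libraries alone. TGF-beta pathway genes had a median of 0.36 (percentile 99.30), with Ccn2 (2.12) and Thbs1 (1.51) among 4 higher genes and Id2 (−1.91) among 2 lower genes. In the IgG precipitates neither list lay outside the central 95% of random lists, at percentiles of 75.44 and 78.31. The sphingolipid list was also inside for the difference of the Caprin-1 over IgG ratios. Its median there was 0.07 (percentile 69.36), with no gene past 2-fold. Tgfbr1, which encodes the type I TGF-beta receptor, stood at 0.41 [0.30, 0.51] in the Caprin-1 precipitates and 0.15 [0.07, 0.23] in the IgG precipitates, and its most abundant transcript alone gave −0.30 in the Caprin-1 precipitates.

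Hedgehog pathway genes had a median log2 ratio of 0.08 (percentile 30.17), with Boc (1.63), Ptch1 (1.5) and Cdon (1.31) higher and Hhip, a hedgehog-binding inhibitor gene, lower at −2.06. Wnt and beta-catenin pathway genes had a median of 0.07 (percentile 26.12), with 5 of 35 higher, led by Wnt7a (2.90), and 3 lower, including Wnt10a (−1.74). Epithelial-mesenchymal transition and metastasis genes had a median of 0.10 (percentile 62.30), with 4 of 26 higher and 4 lower. The medians of these 3 lists lay below 0 under trimmed-mean scaling. Postn, which encodes the matrix protein periostin, stood at 4.64, Mmp9 at −1.96 and S100a4 at −1.97. Myc and the cyclin gene Ccnd2, both described as Caprin-1 targets, stood at 0.67 [0.62, 0.72] and 1.26 [1.15, 1.37]. In the IgG precipitates they stood at 0.89 and 1.00. Ctnnb1, which encodes beta-catenin, stood at 0.13 in the Caprin-1 precipitates, a value that fell below 0 under trimmed-mean scaling, and at −0.42 in the IgG precipitates. Under total-count scaling the median over all genes was 0.146 in the Caprin-1 precipitates and 0.102 in the IgG precipitates. Under trimmed-mean scaling it was 0.005 and 0.029.

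**Figure D2:**
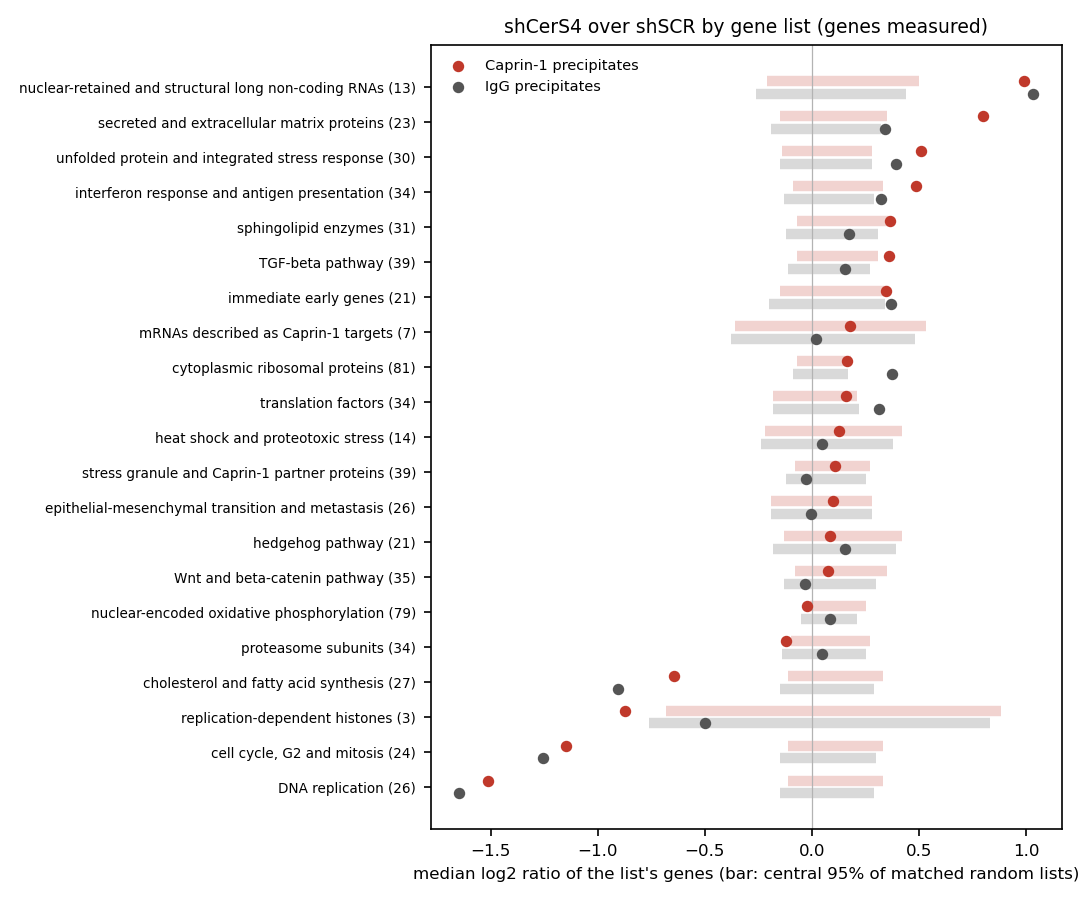
Each row is a gene list with its number of measured genes in brackets, and the points are the median shCerS4 over shSCR log2 ratios in the Caprin-1 and the IgG precipitates. Bars span the central 95% of 10000 random lists of matched expression, and the DNA replication list lies at −1.51 and −1.65 and the long non-coding RNA list at 0.99 and 1.03.

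Of the 10 lowest genes with a mean of at least 20 CPM, 8 lay close together on chromosome 5 (build GRCm38). A scan of median log2 ratios over windows of 15 neighbouring genes, added after these values were seen, gave −3.81 as the lowest window in the Caprin-1 precipitates and −3.66 in the IgG precipitates. The lowest windows among 1000 shuffled gene orders were −1.19 and −1.17. A run of 27 consecutive measured genes, from Cdk6 (start 3341004) to Elapor2 (end 9484663), was lower in shCerS4 cells in both precipitates, 23 of them past 2-fold in the Caprin-1 precipitates and 25 in the IgG precipitates. The median log2 ratio of the run was −2.11 with Caprin-1 and −2.06 with IgG. From Steap4 to Elapor2, a part that holds Abcb1a (8567091 to 8748575) and Abcb1b (8798147 to 8866314), the medians were −3.81 and −3.95. Cyp51 of the cholesterol list and Fzd1 of the Wnt list lie within the run. Reads of Abcb1a and Abcb1b, which are close paralogs, may be divided between them with some error.

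**Figure D3:**
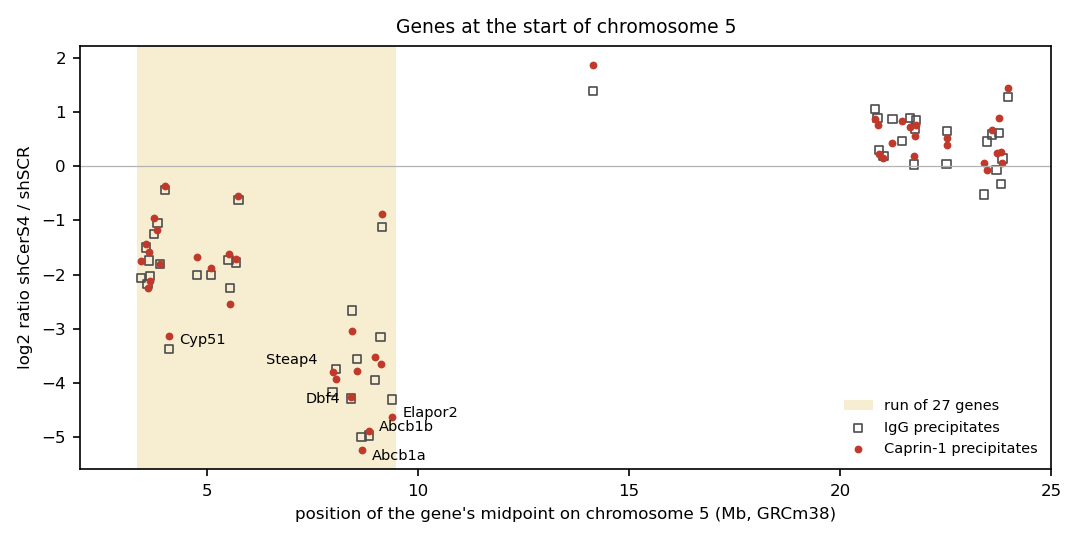
Points are genes at the start of chromosome 5 by the midpoint of the gene in Mb, with the shCerS4 over shSCR log2 ratio in Caprin-1 (filled circles) and IgG precipitates (open squares). The shaded stretch marks the run of 27 genes, whose Caprin-1 ratios lie between −0.36 and −5.24.

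Caprin-1 precipitates were next compared with IgG precipitates within each cell line, to see which transcripts held a larger share with Caprin-1. Each library was scaled to its own total, and no measure of RNA yield was used. The ratios are therefore relative to the other genes, and a ratio below 0 does not mean less RNA than with IgG. By their medians, the oxidative phosphorylation and proteasome lists were on the enriched side in both cell lines. The TGF-beta, Wnt and stress granule lists were on the depleted side, with most genes of all 5 lists under 2-fold. Across genes this ratio fell with genomic span, at Spearman correlations of −0.54 in shSCR and −0.48 in shCerS4 cells. The list percentiles of this ratio were matched on mean expression and not on span, so a part from gene length was not separated. In shSCR cells 174 genes were higher and 1337 lower past 2-fold with Caprin-1 than with IgG, and in shCerS4 cells 96 were higher and 825 lower. Among genes with a mean of at least 20 CPM, the 8 highest log2 ratios in shSCR cells included those of Higd2a (1.60), Comtd1 (1.57), S100a11 (1.54), Bola1 (1.45), Smarcb1 (1.45), Alkbh7 (1.43) and Snrpb (1.42). In shCerS4 cells they were those of Alkbh7 (1.53), Tfpt (1.40), Aldh3a1 (1.37), Sting1 (1.36), Csnk2b (1.33), Yipf1 (1.30), Atp5d (1.24) and Mrpl46 (1.22). The lowest in shSCR cells were Ptgds, a prostaglandin D synthase gene (−3.17), the osmotic stress factor gene Nfat5 (−2.65), Igip (−2.56), Dnal1 (−2.49), Kmt2a (−2.38), Pou2f1 (−2.37), the nuclear RNA Malat1 (−2.37) and Lpp (−2.34). In shCerS4 cells they were Ccnk (−2.71), Nfat5 (−2.35), Tead1 (−2.19), Kdm6b (−2.16), Inhba (−2.15), Fyco1 (−2.11), Hmbox1 (−2.10) and Glrp1 (−2.10).

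Nuclear-encoded oxidative phosphorylation genes had Caprin-1 over IgG medians of 0.54 in shSCR and 0.47 in shCerS4 cells (percentile 100 in both), with 7 and 4 of 79 genes higher past 2-fold. Atp5d stood at 1.40 and 1.24 and Ndufs3 at 1.27 and 0.97. Proteasome subunit genes had medians of 0.48 and 0.40 (percentiles 100 and 99.99), with Psmb2 at 1.02 and 0.89. Interferon response and antigen presentation genes had medians of 0.31 and 0.19 (percentiles 99.89 and 99.11). Cytoplasmic ribosomal protein genes had a median of 0.30 in shSCR cells (percentile 99.65) and 0.08 in shCerS4 cells (percentile 61.06). Translation factor genes had medians of 0.37 (percentile 98.59) and 0.27 (percentile 94.06).

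The lists with the lowest Caprin-1 over IgG medians included genes of the signalling pathways and of Caprin-1's own protein partners. Stress granule and Caprin-1 partner genes had medians of −0.56 in shSCR and −0.51 in shCerS4 cells, with 9 and 6 of 39 lower past 2-fold and none higher, among them Prrc2b (−1.91 and −1.38) and Nufip2 (−1.67 and −1.52). TGF-beta pathway genes had medians of −0.60 and −0.43, with Smad5 at −1.75 and −1.10, Bmpr2 at −1.52 and −1.11 and Tgfbr1 at −1.34 [−1.44, −1.24] and −1.09 [−1.18, −1.0]. Wnt and beta-catenin pathway genes had medians of −0.47 and −0.46, with Fzd3 at −1.86 and −1.59 and Gsk3b at −1.80 and −1.81. All 3 lists lay below percentile 2.5 in both cell lines. Among the mRNAs described as Caprin-1 targets, Actb stood at 0.88 and 0.68, Myc at 0.14 and −0.08, Ccnd2 at −1.82 and −1.57 and Map1b at −1.98 and −1.25. The median of this list was 0.14 in shSCR and −0.05 in shCerS4 cells, inside the central 95% of random lists in both, and the value in shCerS4 cells lay above 0 under trimmed-mean scaling. Ctnnb1 stood at −0.82 in shSCR and −0.27 in shCerS4 cells.

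The Caprin-1 over IgG log2 ratios of the 2 cell lines, which share no library, had a Pearson and a Spearman correlation across genes of 0.88. In both cell lines 700 genes were lower and 52 higher past 2-fold, where independent lists would share 107.3 and 1.6. These counts depended on scaling. Under trimmed-mean scaling 499 genes were higher and 851 lower in shSCR cells, and 217 higher and 567 lower in shCerS4 cells. The median over all genes then moved from −0.132 to 0.069 and from −0.107 to 0.027, and the Myc ratio in shCerS4 cells was no longer below 0.

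**Figure D4:**
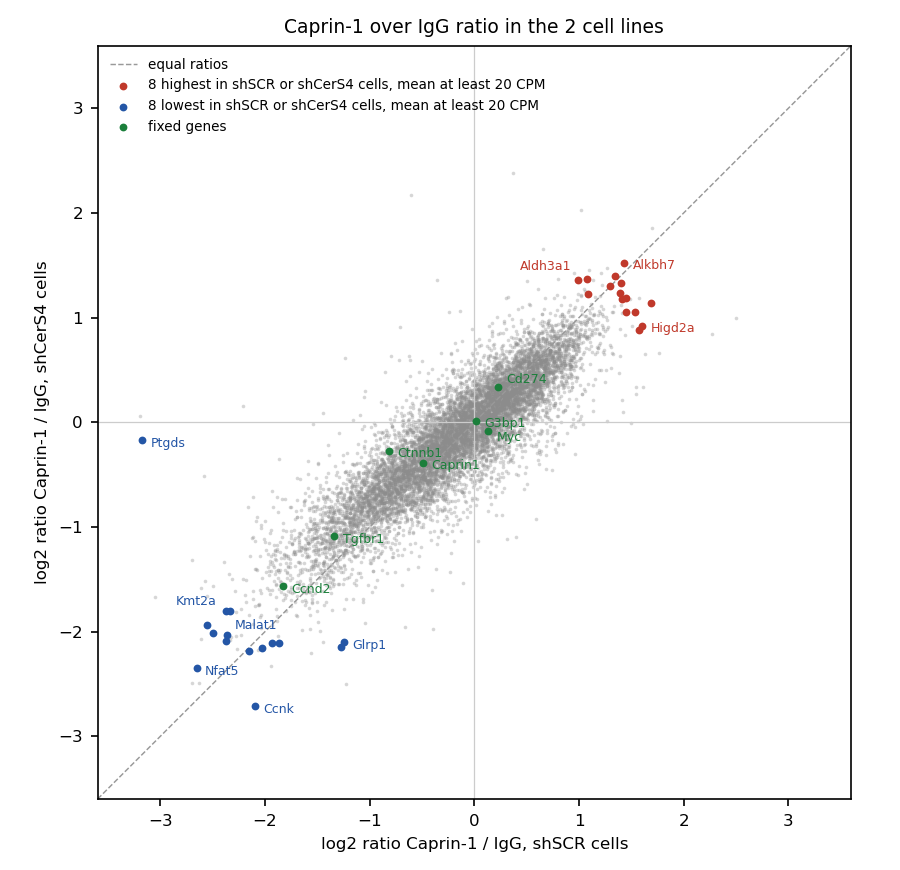
Each point is 1 of the 10283 genes, with its Caprin-1 over IgG log2 ratio in shSCR cells on the horizontal axis and in shCerS4 cells on the vertical axis, and a subset of the named genes is labelled. The 2 ratios had a correlation of 0.88, and Ptgds is a gene far from the line of equal ratios, at −3.17 and −0.17.

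**Figure D5:**
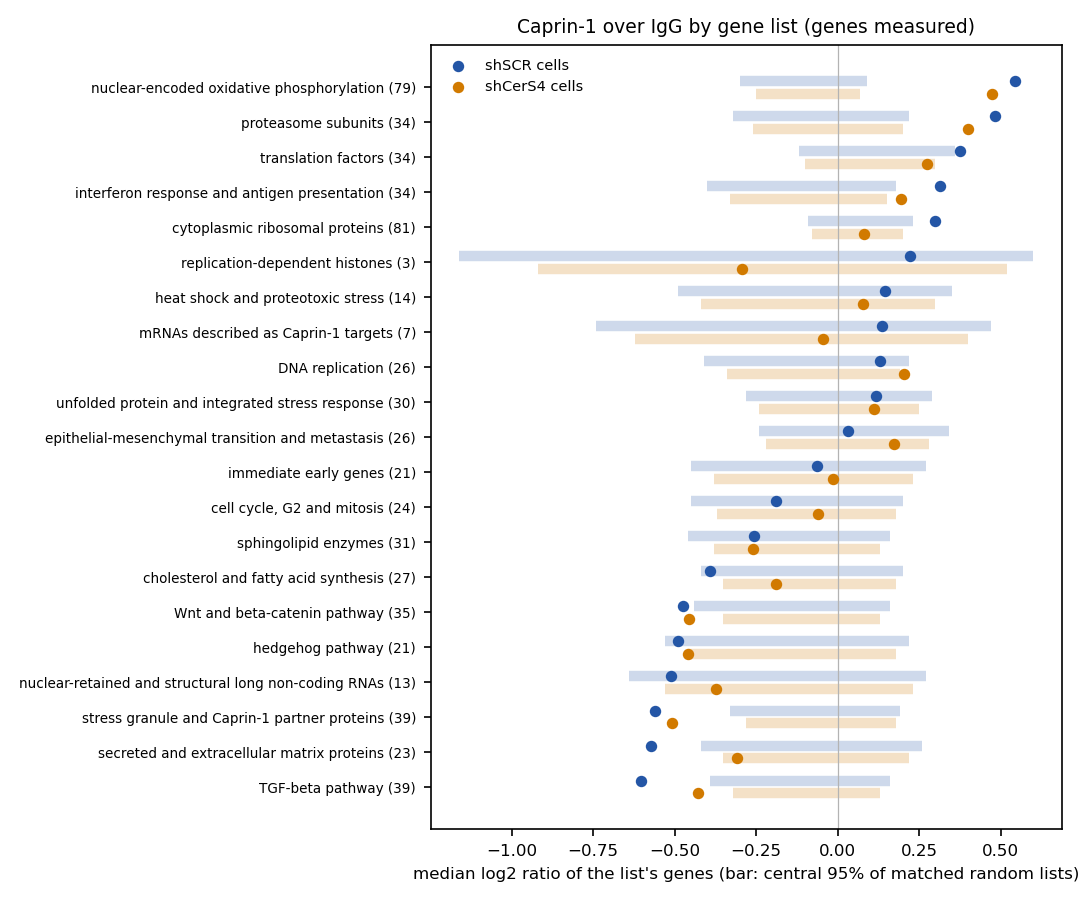
Each row is a gene list with its number of measured genes in brackets, and the points are the median Caprin-1 over IgG log2 ratios in shSCR and shCerS4 cells. Bars span the central 95% of matched random lists, and the oxidative phosphorylation list lies at 0.54 and 0.47 and the TGF-beta list at −0.60 and −0.43.

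The last comparison asked whether the Caprin-1 over IgG ratio itself differed between shCerS4 and shSCR cells, which takes out what both precipitates of a cell line share. Of 10283 genes, 65 had a ratio at least 2-fold higher in shCerS4 cells and 36 at least 2-fold lower, and 8 and 3 of these had a mean of at least 20 CPM. Under trimmed-mean scaling the counts were 48 and 49, with a filter of 1 CPM they were 230 and 177, and with the most abundant transcript of each gene alone 278 and 174. The named higher genes were Ptgds at a log2 difference of 3.0 [2.71, 3.30], Birc6, which encodes a large apoptosis inhibitor, at 1.40 [1.18, 1.63], Cdsn at 1.30, Nbea at 1.14, the collagen gene Col4a5 at 1.13, Vps13b at 1.10 and Pkd1 at 1.02. Ptgds stood at 79.0 CPM in the shSCR IgG library. It stood at 8.73, 15.8 and 14 CPM in the shSCR Caprin-1, shCerS4 IgG and shCerS4 Caprin-1 libraries, so its difference rested mainly on 1 IgG library. Birc6 (−2.11 in shSCR and −0.71 in shCerS4 cells) and Col4a5 (−1.67 and −0.54) had Caprin-1 over IgG ratios below 0 in both cell lines. For these genes higher meant less far below 0, whereas Cdsn went from −1.06 [−1.62, −0.51] to 0.24 [0.13, 0.36]. Cdsn had only 72 and 47 estimated reads in the shSCR IgG and Caprin-1 libraries. It passed the CPM filters through the shCerS4 libraries alone. The 3 lower genes were Hmgn5, a nucleosome-binding protein gene, at −1.42 [−1.63, −1.21], Taf15, an RNA-binding protein gene, at −1.29 [−1.38, −1.19] and Hirip3 at −1.04 [−1.23, −0.84]. Of the 643 genes higher in shCerS4 Caprin-1 precipitates, 18 were also past 2-fold higher by this measure, and of the 509 lower genes 9 were also lower. Independent lists would share 4.1 and 1.8, and 2 of the higher and 4 of the lower genes were past 2-fold in the opposite direction. These comparisons share the Caprin-1 libraries, so part of that overlap may come from them.

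Secreted and extracellular matrix genes had a median log2 difference of 0.25 (percentile 99.96), with Agrn at 0.62 and, in the other direction, the chemokine genes Ccl2 at −0.78 and Ccl5 at −0.69, and none of its 23 genes was past 2-fold. Cholesterol and fatty acid synthesis genes had a median of 0.23 (percentile 99.96), but the 1 of 27 genes past 2-fold, the isomerase gene Idi1, was lower at −1.58 [−2.11, −1.05]. TGF-beta pathway genes had a median of 0.18 (percentile 99.89), with Smad5 at 0.64, Ltbp1 at 0.56 and Thbs1 at 0.54, and none of its 39 genes was past 2-fold. Tgfbr1 stood at 0.25 [0.12, 0.38] when its transcripts were summed and at −0.42 when its most abundant transcript was used alone. DNA replication genes had a median of 0.15 (percentile 98.19) and stress granule and Caprin-1 partner genes of 0.15 (percentile 99.48). Ribosomal protein genes had a median of −0.20 (percentile 0.00), oxidative phosphorylation genes of −0.14 (percentile 0.00), proteasome genes of −0.09 (percentile 0.52) and Caprin-1 target mRNAs of −0.20 (percentile 2.08). Ctnnb1 stood at 0.55 [0.52, 0.57], Ccnd2 at 0.26, Cd274 at 0.11 [0.02, 0.20] and Myc at −0.22 [−0.29, −0.14]. Under trimmed-mean scaling the Cd274 interval held 0. Caprin1 itself stood at 0.11, a value that turned to −0.09 when the most abundant transcript of each gene was used alone.

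Across genes the difference had a Spearman correlation of 0.29 with genomic span, and its median was −0.08 in the 2570 genes with the shortest span and 0.15 in the 2570 with the longest. Random lists matched on the mean Caprin-1 over IgG ratio, and others matched on span, were both chosen after seeing the data. Inside the central 95% of both lay the TGF-beta list (percentiles 93.00 and 96.98), the stress granule list (64.72 and 88.02), the proteasome list (24.71 and 4.47) and the Caprin-1 target list (2.67 and 2.60). The ribosomal protein list (0.00 and 0.18), the oxidative phosphorylation list (0.55 and 0.35), the cholesterol list (99.76 and 99.82), the secreted list (99.45 and 99.86) and the DNA replication list (99.72 and 98.02) stayed outside both. Neither set was matched on the shCerS4 over shSCR ratio in the IgG precipitates. On that ratio, the Caprin-1 ratio had a slope of 0.89 across genes. Lists far from 0 with IgG thus tend to a difference of the opposite sign. That was the direction of the DNA replication (−1.65), cholesterol (−0.91) and ribosomal protein (0.37) lists, and a part from this was not separated. The secreted list (0.34) went the other way. The histone list, with 3 of 47 genes measured and a median of −0.43 (percentile 1.06), was outside lists matched on the ratio (1.00) and inside those matched on span (3.26), and relative to all genes it turned to 0.25 with a filter of 1 CPM. The immediate early list, at 0.08 (percentile 76.90), was inside lists matched on the ratio (73.90) and outside those matched on span (97.68).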

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

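Of all genes that the naming rule selects, those here were flagged because their Caprin-1 over IgG ratio had opposite directions in the 2 cell lines, with intervals that excluded 0. The difference was not tested, since each group had 1 library. Ndufb4, of oxidative phosphorylation, stood at −0.85 in shSCR and 0.48 in shCerS4 cells, a difference of 1.34. Cdsn stood at −1.06 and 0.24, a difference of 1.30, with only 72 and 47 estimated reads in the shSCR IgG and Caprin-1 libraries. Ddit3 stood at 0.19 and −0.35, a difference of −0.54, and Scap, of cholesterol synthesis control, at −0.33 and 0.15, a difference of 0.48. These 4 kept opposite directions under trimmed-mean scaling, with intervals that excluded 0.

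Under that scaling Pold1, Psmd2, Ndufc1, Tmem243, H2ac23 and Rpl29 still had opposite signs, but the interval in 1 of the 2 cell lines held 0. Mmp9, Psmd1, Cyp51, Myc and Hsp90ab1 then had ratios above 0 in both cell lines. Under total-count scaling the ratio was higher in shCerS4 cells for Pold1 (−0.23 and 0.36, difference 0.59), Psmd2 (−0.21 and 0.19, difference 0.40), Mmp9 (−0.12 and 0.26, difference 0.38), Psmd1 (−0.09 and 0.28, difference 0.37) and Cyp51 (−0.08 and 0.16, difference 0.24). The ratio was lower in shCerS4 cells for Ndufc1 (0.32 and −0.24, difference −0.56), Tmem243 (0.15 and −0.36, difference −0.51), the histone gene H2ac23 (0.22 and −0.29, difference −0.51), Rpl29 (0.30 and −0.16, difference −0.46), Myc (0.14 and −0.08, difference −0.22) and Hsp90ab1 (0.09 and −0.10, difference −0.19).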

How the results depend on the processing

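Scaling moved the counts of Caprin-1 over IgG. Under trimmed-mean, median-of-ratios and upper-quartile scaling 499, 448 and 461 genes were higher in shSCR cells instead of 174, and 217, 229 and 243 in shCerS4 cells instead of 96. Lower genes in shSCR cells went from 1337 to 851 under trimmed-mean scaling, and in shCerS4 cells from 825 to 549 under median-of-ratios and 537 under upper-quartile scaling. The overlap of the 2 cell lines was then 146, 150 and 156 higher genes instead of 52 and 446, 444 and 435 lower genes instead of 700. Ctnnb1 in Caprin-1 precipitates was −0.013 under trimmed-mean scaling, and Myc over IgG in shCerS4 cells was 0.052, 0.060 and 0.066 under the 3 scalings. Leaving the 50 most abundant genes and ribosomal RNA out of the totals gave 259 higher and 1158 lower genes in shSCR cells and 134 and 713 in shCerS4 cells, and moved the median over all genes in shSCR cells from −0.132 to −0.063, against 0.069 under trimmed-mean scaling. For the rest of these shifts the cause was not tested.

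The filter changes the number of genes by construction. Between cell lines, Caprin-1 precipitates had 353 higher and 333 lower genes at 20 CPM and 1270 and 927 without a filter. IgG precipitates had 297 and 338 at 20 CPM, 1238 and 1181 without a filter, and 884 higher at 1 CPM. Over IgG in shSCR cells 262, 113 and 418 genes were higher at 1 CPM, 20 CPM and without a filter, with 2050 lower without a filter. In shCerS4 cells 187, 53 and 356 were higher and 1359 lower without a filter. The difference of the ratios had 230 and 177 genes at 1 CPM, 8 and 3 at 20 CPM, and 457 and 311 without a filter. Overlaps were 216 higher between precipitates at 20 CPM, 716 higher and 635 lower without a filter, and 96 higher between cell lines without a filter. The correlation of 0.892 between precipitates was 0.820 at 1 CPM and 0.553 without a filter, and that of 0.877 between cell lines was 0.737 and 0.367. Relative to all genes, the histone list in the difference of ratios was at 0.25 at 1 CPM, and the immediate early list in IgG precipitates at −0.016 at 1 CPM and −0.009 without a filter, both reversed.

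With the most abundant transcript per gene, chosen after seeing the data, 265 and 181 genes were higher over IgG in shSCR and shCerS4 cells. The difference of the ratios then had 278 higher and 174 lower genes, and the correlations were 0.792 and 0.747. Caprin1 was at −0.09 in the difference, and Tgfbr1 at −0.30 in Caprin-1 precipitates and −0.42 in the difference, all reversed, and the cause was not tested. Leaving out the chromosome 5 genes and matching random lists on the ratio or on genomic span were also chosen after seeing the data. The length and GC trend was not run, since the reference held neither. No paired test was made, since the libraries pair only by cell line and antibody, with 1 library each. The Caprin-1 over IgG ratios within each cell line use that pairing. Leaving out 1 library at a time was impossible with 1 library per group.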

Other observations

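Immediate early genes had a median log2 ratio of 0.35 between cell lines in Caprin-1 precipitates (percentile 96.58) and 0.37 in IgG precipitates (percentile 98.67), where relative to all genes it turned to −0.016 with a filter of 1 CPM and −0.009 without a filter. Of 21 genes 6 were higher past 2-fold with Caprin-1, including Fosl2 (1.89), Jund (1.19) and Btg1 (1.10), and 2 lower, including Egr1 (−1.20). Heat shock genes had medians of 0.13 and 0.05, both below 0 under trimmed-mean scaling, with 1 of 14 lower, Hspb1 (−2.23). Of the 3 measured histone genes H2ac23 stood at −3.03, and the list median was −0.87 (percentile 1.25). Ribosomal protein genes had medians of 0.16 with Caprin-1 (percentile 94.99) and 0.37 with IgG (percentile 100), and translation factor genes of 0.16 and 0.31, with no member past 2-fold. Oxidative phosphorylation genes had a median of −0.02 (percentile 1.69), proteasome genes of −0.12 (percentile 1.57) and stress granule genes of 0.11 (percentile 52.36), again with no member past 2-fold. The stress granule median lay below 0 under trimmed-mean scaling. Caprin-1 target mRNAs had a median of 0.18 (percentile 63.02).

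Over IgG, the long non-coding RNAs Neat1 (−1.39 and −1.43) and Norad (−1.51 and −1.53) were lower past 2-fold in shSCR and shCerS4 cells, within a list at −0.51 and −0.37 that lay inside random lists. Hedgehog genes were at −0.49 and −0.46, sphingolipid genes at −0.26 and −0.26, and secreted genes at −0.57 (percentile 0.38) and −0.31 (percentile 4.34). The mitosis list was at −0.19 and −0.06, the epithelial-mesenchymal list at 0.03 and 0.17, with the keratin gene Krt18 at 1.16 and 0.95. Both mitosis medians lay above 0 under trimmed-mean scaling. In the difference of the ratios the epithelial-mesenchymal list had 1 gene past 2-fold, the integrin gene Itgb3 (1.19). Few markers of other tissues were measured, with Pdgfra of fibroblasts at 35.3 CPM on average and Cd68 of macrophages at 49.1 CPM in the shSCR and 14.6 CPM in the shCerS4 Caprin-1 precipitate. The Cd68 log2 ratio was −1.75 with Caprin-1 and −0.79 with IgG, a difference of −0.96. Also measured were, of small structured RNAs, Rmrp (6.08 CPM) and Rpph1 (11.2 CPM).

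The tests of the cell line difference and of the chromosome 5 run were chosen only after these results were seen, and those of the low Caprin-1 over IgG ratios before.

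The difference between Caprin-1 precipitates may reflect RNA levels of the cell lines that both precipitates carry. Of the 1152 genes past 2-fold, 98.5% had the same direction in IgG precipitates with an interval that excluded 0, and 70.2% were past 2-fold there. A change in what Caprin-1 binds is unlikely as the main source of these differences. Of the genes, 2.3% were past 2-fold in the same direction in the difference of the Caprin-1 over IgG ratios. A smaller part stays open, since 412 genes (35.8%) had that direction with an interval that excluded 0 and 143 had the opposite one. The genes were chosen by their Caprin-1 ratios, and the same libraries enter the difference. Error in those libraries favours the same direction, so this excess does not measure a change in binding. Under total-count scaling only 174 genes in shSCR and 96 in shCerS4 cells were past 2-fold above IgG. These libraries may thus show little of what Caprin-1 binds. A change in binding could stay below 2-fold here, and whether binding changed was not settled. Under trimmed-mean scaling 1081 genes were past 2-fold. Scaling moves every log2 ratio by the same amount, so that total could hardly have fallen by much and decides nothing about scaling. The balance did turn, from 643 higher and 509 lower genes to 442 and 639. A second culture of each line with input RNA would test the source of the difference.

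Low Caprin-1 over IgG ratios in both cell lines may come with gene length, since the ratio had a Spearman correlation of −0.54 with genomic span in shSCR and −0.48 in shCerS4 cells. The 2570 genes with the longest span had medians of −0.70 and −0.54, though span is not transcript length. Whether nuclear or non-coding RNA carried over more in IgG precipitates cannot be told apart, with long non-coding genes differing from protein-coding genes by 0.03 and −0.06. The count of lower genes, summed over both cell lines, was 2150 after thinning to equal depth and 2162 before. Thinning leaves the expected ratios as they were, so the count could hardly fall. This comparison cannot decide whether deeper Caprin-1 libraries played a part. Transcript lengths and RNA integrity values would test the source of the low ratios.

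The run of 27 genes on chromosome 5 may differ in RNA between the cell lines as a region, since its IgG median was −2.06. The same 27 genes form the run when it is chosen from the Caprin-1 libraries alone. In the shSCR and shCerS4 IgG libraries Abcb1b stood at 2535 and 80.8 CPM and Dbf4 at 1581 and 80.7 CPM. Whether RNA of the run fell in shCerS4 cells or rose in shSCR cells cannot be told, since no parental cells were sequenced. A change in what Caprin-1 binds is unlikely, at a median difference of the ratios of 0.06. Without the Abcb genes the Caprin-1 median was −1.88, so reads shared between them do not account for the low ratios of the other genes. Since the run was chosen for low ratios, that median could hardly have been otherwise. It cannot tell how far shared reads affect Abcb1a and Abcb1b. Chance gene order is unlikely too, since 0 of 1000 shuffled orders gave a window as low. A difference in copy number around the Abcb1 transporter genes could arise under puromycin, a known substrate of the transporter that was in the medium of both lines, but DNA was not measured. Copy number of this region in both lines would test it.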
